A study of Homo sapiens with 6 samples.

How the data were processed

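RNA from 6 libraries of U-87 MG cells, 3 with DMSO (10 ul per 10 ml of medium) and 3 with EPZ015666, was poly(A)-selected and sequenced, per the labels' protocols. The submitters' processing notes name STAR 2.4.1d, Bowtie 1.0.1, bedtools 2.20.1, DESeq 1.10.1 and RSEM, and the builds hg19 and GRCh37, without saying which step each served. The deposited file analysed here is 1 exon annotation of 9 columns. Its only numeric columns, per the deposited rows, are the start and end position of each exon, and 0 rows held a number elsewhere outside the names. Expression tables were not analysed here. The planned tests of expression and of detained intron levels between the groups were therefore not run, and depth and replicate spread are unknown. No genome of the files' build was used here, so GC content and splice site strength were not tested. Coding sequence is not marked in the rows, so the test of lengths in multiples of 3 was not run.

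Rows were split into isoforms where the parent name changed or the order along the strand restarted, which gave 31659 isoforms. Exons whose end preceded their start (76 rows) were dropped. Consecutive exons of an isoform overlapped in 10093 places, 87.4% of them at the last pair of the isoform, and the later exon was kept. The isoform with the most introns served as the reference isoform of a gene.

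The tests planned for detained introns, before the data were examined, were run on spanned introns, because no row marks a detained intron. This changes what the tests measure, and their results say nothing of detention. Final exons, joined exons, the coverage of gene lists and the introns that hold an early final exon were chosen after seeing the file.

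Gene names were matched to GENCODE v29, a GRCh38 annotation, by name (12493) or an older symbol (4). Reference and file were compared by exon and intron lengths within a gene and never by position. Of 131295 introns in matched genes, 91.5% had an intron of the same length in the reference gene. There were 68 matched names on another chromosome or strand than in the reference, and 55 matched genes with 3 or more introns shared no intron length with it. For 27 of these, at least 3 introns and at least 50% of all introns had lengths found in another gene. Some of these matches rest on 3 or 4 introns and may be coincidence, such as those of AC023490.1 and SNX29P2 to TTN. LRRD1 had 10 of 10 intron lengths of CYP51A1, and MIR3654 had 9 of 9 of EEF1G. Names are given as in the file. A joined exon had to equal a run of consecutive reference exons exactly in length, with at least 1 flanking intron of the same length, and to equal no single reference exon of the gene.

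The 23 gene lists were fixed before the data were examined. Lists with at least 8 background members were tested by an exact conditional Mantel-Haenszel test (two-sided) stratified on 5 bins of intron number, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. The background was genes with at least 1 intron, or, for joined exons, matched genes with at least 2. Coverage of the lists, and of 1 further list of genes used in other tissues, was tested by Fisher's exact test. Within-gene tests were two-sided, with genes as units and 100000 resamples. Intervals of shares are 95% Wilson intervals and cover counting error only. Genes are not independent replicates, and no p-value here refers to variation between cultures.

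Genes were named by a rule fixed before the data were examined: the 10 genes with most such introns, up to 4 members of each tested list, a fixed set of PRMT5 partners, CLK kinases, SR proteins, MDM4, CDK4 and EGFR, and the 3 longest and 3 shortest introns. The same rule was applied to final and joined exons. Another gene of the fixed set, and 1 tested list, are not reported here. LUC7L3 falls outside it and was named after its values were seen, to complete a count.

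Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and R 4.3.3. The methods were tested on simulated data. For the list test on 12462 genes, a list given a 4-fold odds passed in 88% of 50 simulations, with a median recovered odds ratio of 3.81, and 0.118% of unchanged lists passed. That list was DNA damage repair, with 87 genes, so the 88% does not hold for the shorter lists, which were not simulated in this way. With no effect, the test of first or last introns on 300 genes passed in 6.67% of 300 simulations. Of 392 joined exons planted in reference transcripts, 392 were recovered, and 0 of 4057 unmerged exons were called. Both outcomes were fixed by the definition, since planted and unmerged exons came from the reference itself. They check the code and give no error rate for the deposited annotation. Alternatives were other strata, other gene sets, medians, first introns left out, overlap in place of exact matches, pooled introns and the other choice among overlapping exons.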

Results

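Poly(A)-selected RNA was sequenced from U-87 MG cells, an established human glioma line, in 2 groups of 3 libraries. The cells had received DMSO, the vehicle, or 10 uM EPZ015666, an inhibitor of the arginine methyltransferase PRMT5, for 72 h. The series asks how PRMT5 activity bears on detained introns, which are introns left in otherwise spliced, polyadenylated nuclear RNA. The file analysed here is 1 exon annotation made for both groups together, in hg19 coordinates. It has 0 columns of values per library, so no level, depth or replicate error can be given and no comparison of EPZ015666 with DMSO was made. The submitters describe it as covering both detained introns and coding isoforms. None of its rows marks an intron as detained in its names (0 of 382567 exon rows), so which entries stand for detained introns, if any, could not be told from the rows. The results below therefore describe the gene structures listed for these cells, and they do not show an effect of the inhibitor.

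The annotation listed 13721 gene names, 12462 of them with at least 1 intron, and 138855 distinct introns. The median gene had 8 introns (quartiles 5 and 14), and the median intron was 1471 bases long. Of the 19936 protein-coding gene names of the GENCODE v29 reference, 12244 (61.4%) had a listed isoform. Of the 13721 names, 12497 were matched to the reference, 4 of them by an older symbol. Listed genes under unmatched names, such as MRE11A and WHSC1, count as unlisted here, so the share may be too low.

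Genes of basic cell processes were nearly all listed. Markers of neurons, oligodendrocytes, myeloid and endothelial cells were listed in smaller shares than those genes, a difference that was not tested. Against other protein-coding genes, neuron markers were listed more often (odds ratio 1.89). Oligodendrocyte and myeloid markers (0.31 each) and endothelial markers (0.38) were listed less often. These marker lists are short, and none passed that test. Among chromatin modifiers 86 of 87 protein-coding symbols had an isoform (98.9%, 95% Wilson interval 93.8 to 99.8). List symbols that are no protein-coding name of the reference are left out of the counts in this paragraph, which can therefore differ from later counts of list members. The spliceosome list, which holds components of the U2 and U5 particles and of the PRP19 complex, had 59 of 60, and mitosis and cell cycle genes had 89 of 91. All 22 glycolysis genes and all 5 PRMT5 methylosome genes that could be matched were listed. Extracellular matrix and adhesion genes had 51 of 52. Neuron markers had 9 of 12 (interval 46.8 to 91.1%). Oligodendrocyte and myeloid markers each had 3 of 9 (33.3%, interval 12.1 to 64.6), and endothelial markers had 3 of 8 (37.5%, interval 13.7 to 69.4). By Fisher's exact test (two-sided, Benjamini-Hochberg adjusted over the lists), the share of chromatin modifiers lay above that of other protein-coding genes (adjusted p = 5.42e-16). Unmatched names lower the share of the other genes but are left out of a list, so these comparisons are tilted toward the lists. The oligodendrocyte and myeloid lists did not pass the exact test (adjusted p = 0.111 for each), nor did the endothelial list (adjusted p = 0.286) or the neuron list (adjusted p = 0.391).

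Among the genes named in advance, PRMT5 (chromosome 14, 23389739 to 23398661) was listed with 18 introns and 1 final exon. Its partner WDR77 (chromosome 1, 111982513 to 111991830) had 10 introns and 1 final exon. CLNS1A, the chloride channel regulator that binds PRMT5 and Sm proteins, had 6 introns and 2 final exons. The kinases CLK1, CLK2 and CLK3, which phosphorylate SR proteins, each had 1 final exon and no spanned intron, as defined below, while CLK4 had 3 final exons and 1 spanned intron. CDK4, a cell cycle kinase gene, had 7 introns and 1 final exon. EGFR had 27 introns and 4 final exons. MDM4 had 2 final exons on chromosome 1 (204485508 to 204516005). Of the SR proteins, SRSF1, SRSF5 and SRSF11 each had 2 final exons and SRSF10 had 4. SRSF2, SRSF3, SRSF4, SRSF6, SRSF7 and SRSF9 each had 1.

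Many genes were listed with more than 1 final exon. A final exon is defined here by its acceptor, the 5' edge of the last exon of an isoform. Ends named below are those of listed exons, and whether they are transcript ends in the cells was not tested. Of the 12462 genes with introns, 2802 (22.5%, interval 21.8 to 23.2) had 2 or more final exons. There were 1867 with 2, 601 with 3, 205 with 4 and 129 with 5 or more. ANKRD11, a chromatin regulator, had 14, and the histone demethylase gene KDM4C and ADAMTSL1 had 10 each. PPP2R5C, a regulatory subunit of protein phosphatase 2A, had 9. Of the 7078 final exons in these genes, 2836 (40.1%) shared their acceptor with an internal exon. The file numbers isoform groups within a gene, and what the numbers stand for is not given in the sources used here. Of 2375 genes with 2 or more groups, 1735 (73.1%) had no final exon acceptor shared between groups.

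The share of genes with 2 or more final exons was 36.8% for DNA damage repair (32 of 87, interval 27.4 to 47.3) and 35.6% for chromatin modifiers (31 of 87, interval 26.4 to 46.1). It was 15.7% for mitosis and cell cycle genes (14 of 89, interval 9.61 to 24.7) and 10.4% for oxidative phosphorylation (7 of 67). These genes also differ in intron number. With intron number held in 5 bins, 0 of 19 lists passed the exact Mantel-Haenszel test after adjustment, and 2 had an unadjusted p under 0.05. These were mitosis and cell cycle (odds ratio 0.48, 95% interval 0.25 to 0.86, p = 0.0106, adjusted p = 0.201) and neuron markers (5 of 8 genes, odds ratio 5.13, interval 0.94 to 34.8, exact p = 0.0299, adjusted p = 0.284). For 3 or more final exons the neuron odds ratio was 1.38 (adjusted p = 0.956, exact test). Members with several final exons included GAD1, MAP2, RBFOX3 and SYN1 among neuron markers.

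**Figure D1:**
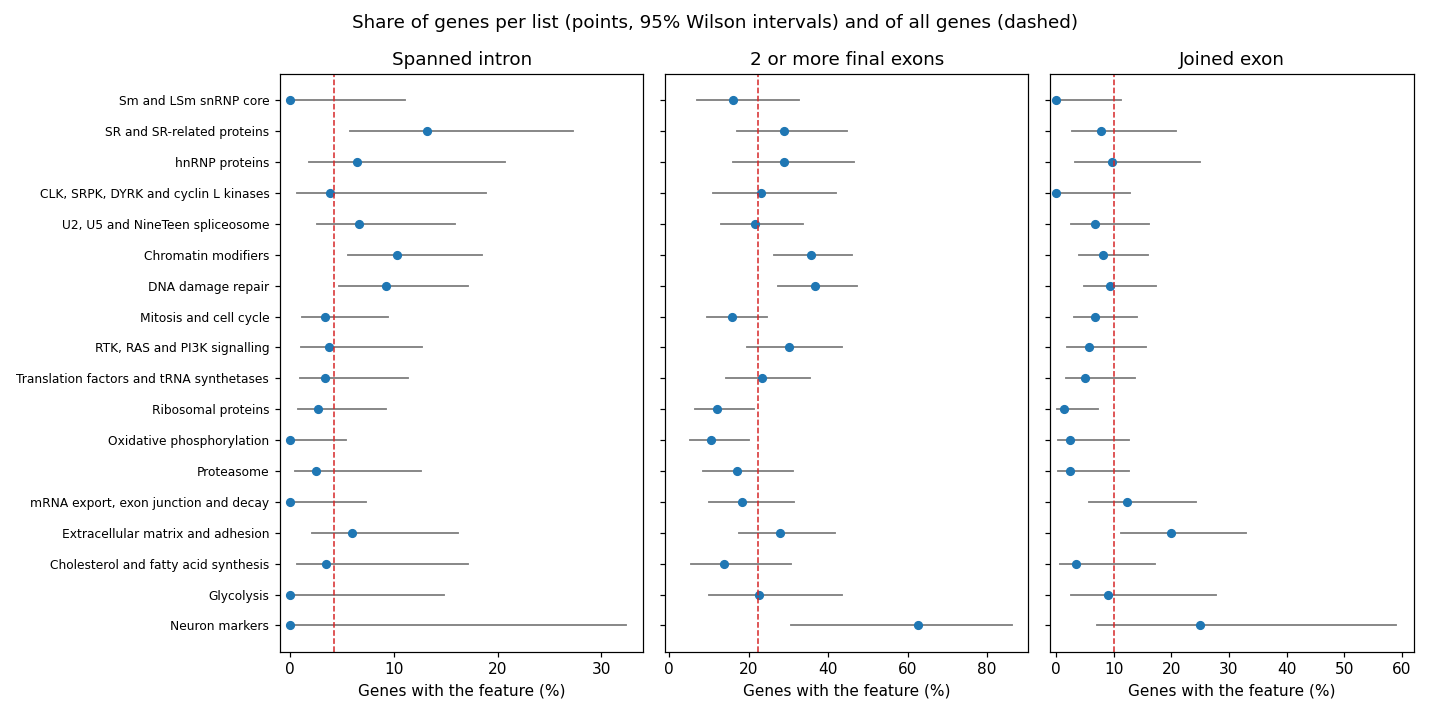
Percent of genes in each list drawn (points, with 95% Wilson intervals) that had a spanned intron, 2 or more final exons or a joined exon, with the percent among all genes compared as a dashed line. The dashed lines lie at 4.18%, 22.5% and 10.1%, and 0 of 19 lists passed the adjusted test in any of the panels, counting 1 list that is not drawn. All genes with a spanned intron are also among those with 2 or more final exons.

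Some introns were listed both as spliced and inside a single exon whose ends match the exons on both sides. These are called spanned introns. There were 653 in 521 genes (4.18% of genes, interval 3.84 to 4.55), 414 of which held 1. Introns that share 1 edge and differ at the other are counted separately. Every one of the 653 lay inside a final exon and 0 lay inside an exon that was not final, so each is listed as a final exon that runs on through an intron. The isoform with that intron spliced has another final exon. All 521 genes were therefore also among those with 2 or more final exons, and the 2 features overlap by definition. Whether any of them is detained was not tested. PPP2R5C had 5, and SLC39A11, a zinc transporter gene, had 4, and in both genes some of them share an edge. In EIF3E, which encodes a subunit of a translation initiation factor (chromosome 8, 109213973 to 109260959), the intron from 109245902 to 109247226 was spanned. The shortest and longest spanned introns were 28 bases in CENPN and 165395 bases in ANK2. The 28-base one shares an edge with a 56-base one, and neither is on the CENPN isoform with the most introns. Whether such short gaps are spliced introns was not tested.

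**Figure D2:**
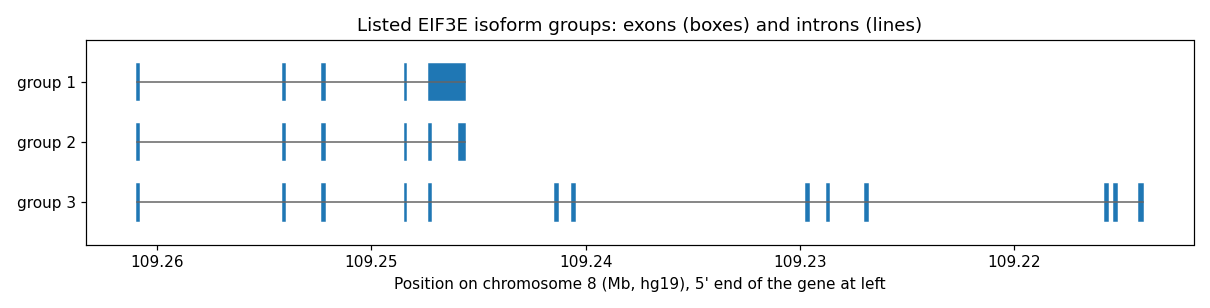
Exons (boxes) and introns (lines) of the 3 listed EIF3E isoform groups along chromosome 8 in Mb of hg19, with the 5' end of the gene at left. The final exon of group 1 covers the intron that group 2 has before its own final exon, and group 3 runs to 13 exons.

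Among SR and SR-related proteins, which take part in splicing, 5 of 38 genes held a spanned intron (13.2%, interval 5.75 to 27.3): LUC7L3, PNN, SCAF11, SON and SRSF10. PNN, SCAF11 and SON had 2 each, and the 2 in PNN share an edge. Chromatin modifiers had 9 of 87 genes, among them ASXL1 with 3 and ING3, KDM4C and WHSC1 with 2 each. The 2 in ING3 share an edge, as do the 2 in WHSC1. DNA damage repair had 8 of 87, including MRE11A, MUS81, PMS1 and RAD51B. The spliceosome list had 4 of 60, with SF3B1 holding 2 that share an edge and CWC27, RBM25 and RBM39 holding 1 each. None of the 67 oxidative phosphorylation genes or 49 export and decay genes with introns had one. By the exact Mantel-Haenszel test, 0 of 19 lists passed after adjustment, and 1 had an unadjusted p under 0.05, the SR list (odds ratio 3.10, 95% interval 0.93 to 8.17, p = 0.0323, adjusted p = 0.615). For genes with 2 or more spanned introns, where introns sharing an edge count separately, the SR odds ratio was 8.82 (exact test, adjusted p = 0.119).

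Spanned introns were shorter than the other introns of their genes and lay further toward the 3' end. Of the 653, 363 in 331 genes lay on the isoform with the most introns, where each could be ranked. Their mean log2 length was 9.86, against 10.78 for the other introns of the same genes. The difference was -0.92 (SD 2.08 over 331 genes), and it was negative in 232 genes and positive in 99 (sign-flip permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give). It was -0.55 where an overlap of at least 50% of the intron sufficed, and -0.54 with all introns pooled. The median length was 750 bases, against 1794. On a scale from 0 at the first intron to 1 at the last, their mean position was 0.605 against 0.475, a difference of 0.130 (SD 0.385, 331 genes, sign-flip permutation test, p = 1e-05). With first introns left out the difference was 0.064 (323 genes, permutation p = 0.00211). The last intron made up 22.3% of them (81 of 363, interval 18.3 to 26.9), where 10.4% would be expected from intron number (permutation test, p = 1e-05). The first intron made up 1.38% (5 of 363, interval 0.59 to 3.18), against 10.4% (permutation test, p = 1e-05). In 28 genes with 2 or more, 23 pairs were neighbours, against 8.35 expected (permutation test, p = 1e-05). An exon that spans the first intron would be the first and the final exon at once, and 1 final exon can cover neighbouring introns, so the position and neighbour results are partly set by what a spanned intron is.

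Other final exons ended inside introns of the longest isoform, and those introns were long. In 1744 genes, the introns that held such an end had a mean log2 length of 12.20, against 10.83 for the other introns of the same genes. The difference was 1.37 (SD 1.77), which is 2.58-fold, and it was positive in 1383 genes (sign-flip permutation test, p = 1e-05). Their median length was 4394 bases, against 1749. They lay further toward the 3' end, at 0.616 against 0.476 (difference 0.140, SD 0.350, permutation p = 1e-05). An end in the first intron often needs an isoform of a single exon, and with first introns left out the position difference was 0.080 (1715 genes, permutation p = 1e-05) and the length difference 1.45.

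Some internal exons were as long as 2 or more consecutive reference exons together with the introns between them. These are called joined exons and were found by length within the gene of the same name. Of 118458 internal exons compared, 1772 in 1109 genes were joined (10.1% of 11012 genes, interval 9.52 to 10.6). Their median length was 2450 bases, and 1281 of them held 1 reference intron while 491 held 2 or more. RYR2, the calcium release channel of heart muscle, had 16, the collagen gene COL11A2 had 15, and TTN, which encodes titin of striated muscle, had 14. The axonemal dynein genes DNAH6, DNAH5, DNAH7 and DNAH1 had 14, 13, 10 and 10. COL4A1, a basement membrane collagen, had 11. Extracellular matrix and adhesion genes had a joined exon in 10 of 50 (interval 11.2 to 33.0%), and ribosomal protein genes in 1 of 74 (1.35%, interval 0.24 to 7.27). With intron number held in bins, 0 of 19 lists passed after adjustment, and 1 had an unadjusted p under 0.05, ribosomal proteins (odds ratio 0.16, 95% interval 0.0039 to 0.90, exact p = 0.0284, adjusted p = 0.403). Joining itself lowers the intron number listed, and with bins of the reference's intron number that odds ratio was 0.48 (exact test, adjusted p = 0.914). In 1109 genes, the reference introns inside joined exons did not differ detectably from spliced introns of the same transcript in log2 length (10.35 against 10.35, SD of the difference 1.70, permutation p = 0.942) or position (p = 0.406).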

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

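No result crossed its threshold under the alternatives run, and the length and position differences of spanned introns and of introns holding early ends kept their sign. Directions did turn in 37 alternatives, 36 of them odds ratios of single lists, so no direction is read from those lists. The lowest adjusted p among the 37 was 0.447, and the cause was not tested. Alternatives for final and joined exons, genes with 2 or more final exons only and the choice among overlapping exons were chosen after seeing the data.

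Without strata, odds ratios for spanned introns turned to 0.627 (ribosomal) and 1.47 (matrix), and for final exons to 0.662 (Sm), 1.03 (CLK), 1.05 (translation), 1.34 (matrix) and 1.01 (glycolysis). With bins of genomic span they turned to 1.15 for spanned introns (matrix), to 0.929 (Sm), 1.01 (CLK), 1.03 (spliceosome), 1.24 (translation), 1.04 (ribosomal), 1.08 (matrix) and 1.35 (glycolysis) for final exons, and to 1.07 for joined exons (hnRNP and glycolysis). With 10 intron bins they were 0.971 (RTK, final) and 0.987 (export, joined). With 2 or more spanned introns they were 0 (hnRNP, repair, ribosomal) and 1.496 (matrix). With 3 or more final exons they were 0 (Sm), 0.832 (repair) and 0.614 (RTK). By numbered groups they were 0.219 (Sm), 0.988 (SR), 1.30 (CLK) and 1.00 (matrix). Among genes with 2 or more final exons only, spanned introns gave 1.16 (mitosis) and 1.44 (cholesterol). With spanned-intron genes left out, final exons gave 0.827 (SR) and 1.08 (glycolysis). Joined exons of 1000 bases or more gave 1.05 (SR), and bins of reference intron number gave 0.745 (export, joined). The log2 length difference of joined introns was 0.0234 with medians, against -0.0037 with means.

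Lists past the adjusted threshold stayed at 0, and those with an unadjusted p under 0.05 ranged from 1 to 3 (spanned), 0 to 5 (final) and 0 to 2 (joined). Keeping the earlier of 2 overlapping exons gave 4.11% of genes with a spanned intron, 22.0% with 2 or more final exons and 10.1% with a joined exon. Spanning exons were sought among all listed exons under either choice. The spanned share could therefore change only through the introns, and its closeness is partly built in. At most 3 spanned introns per gene removed no gene and tested nothing.

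No paired analysis was possible because the file has no columns of libraries. Alternatives for differential expression, GC content, splice site strength and lengths in multiples of 3 were not run, for lack of values, genome sequence or marked coding regions.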

Other observations

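The tests of joined exons in this part were chosen after the result was seen. The test of spanned introns against the reference and that of ends in long introns were written before their results, except that leaving out first introns was chosen afterwards.

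Genes that are mostly used in other tissues were listed less often than other protein-coding genes (Fisher's exact test, adjusted p = 2.54e-05). Of 76 such genes, chosen after RYR2, TTN and the DNAH genes had been seen and leaving these out, 28 (36.8%, 95% Wilson interval 26.9 to 48.1) had a listed isoform. Those listed included UNC13A, a synaptic vesicle gene, with 6 joined exons, CUBN, a kidney and gut receptor gene, with 5, and the thyroglobulin gene TG with 4. The muscle genes ACTN2 and NEB had 3 each. These genes were named after their values were seen.

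Joined exons could arise from chance, from the reference or from sparse evidence of splicing, among other sources. Whether any of them holds a detained intron was not tested. Chance match of lengths is argued against, since lengths shifted by 7 or 13 bases gave a mean of 5 matches against 1772, and the reference annotation holds the same long exon for 14.6% of the 2075 exons that matched a run (303, interval 13.1 to 16.2), which were not counted as joined, so the 1772 equal no reference exon in length by definition. Few spliced reads in genes the cells hardly use remains open as a hypothesis: 18 of 25 tissue-restricted genes had a joined exon, an odds ratio of 20.7 with strata of the listed intron number (exact Mantel-Haenszel, interval 8.16 to 59.4, p = 2.28e-12) and 19.2 without the dynein gene DNAI1. Joining lowers the listed number, and with bins of the reference's intron number, which are broad for the longest genes, the odds ratio was 10.6 (exact test, interval 4.16 to 30.3, p = 2.99e-08). The list was chosen after RYR2, TTN and the DNAH genes had been seen and holds other muscle genes, such as ACTN2 and NEB. Leaving out DNAI1 does not remove these, so the p-values are no independent support. Some of these genes were listed with far fewer introns than the reference, such as NEB (5 against 182), and others with as many, such as ANK1 (42). The strata of listed intron number therefore set partial structures of some long genes beside short genes. Read numbers were not analysed here, and no biological explanation was tested.

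Spanned introns might only repeat exons of the reference. The reference annotation holds both forms, by length, for 15.7% of them (93 of 591, interval 13.0 to 18.9), which argues against this as the whole source. Only GENCODE v29 was compared, so an older annotation as the source stays open. The share for other introns of the same genes was 4.68%. A link between spanned introns and a general excess of isoforms was to be tested only for a gene list past the threshold, and there was none. All 521 genes with a spanned intron had 2 or more final exons, but this follows from the definition and cannot decide that question. No biological explanation was tested.

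Ends inside long introns could follow from room, if ends fell on intron bases in proportion to length, and such introns were long. They were still shorter than strict proportion gives, with a difference of -0.64 on the log2 scale (12.20 against 12.83, SD 1.53 over 1744 genes). Part of that came from first introns, which seldom hold an end (22 of 2062 such introns, against 195 expected from intron number). With first introns left out the difference was -0.41 (SD 1.44, 1715 genes), and -0.38 in the 1459 genes with 1 such intron, of which 723 lay above the expectation and 736 below. Strict proportion is argued against by the bound of 0.2 set beforehand, while room that acts less steeply with length stays open, and no biological explanation was tested.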
